A study of Arabidopsis thaliana and Trichoderma atroviride with 29 samples.

How the data were processed

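Total RNA was extracted with TRIzol, per the labels' protocols, and unstranded TruSeq v2 libraries were sequenced on an Illumina HiSeq as paired reads of 100 nt. Fungal RNA came from the mycelium nearest the root. The labels call the replicates biological. Salmon and edgeR are named in the submitters' processing notes, with no versions. The genome builds and annotations are not given in the sources used here.

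The deposited values are estimated counts per gene, as Salmon gives them, in 1 table for each organism, with 10.1% of the values above 0 not whole in the Arabidopsis table and 9.39% in the Trichoderma table. They were not normalised by the authors as far as the values show, since each library sums to its own total. The estimated counts deposited by the authors were rounded to whole numbers before testing. Every column was matched to a sample by its name, and 0 columns belonged to no sample. The Arabidopsis table holds 32310 genes, of which 5966 have no count in any library, and 11848 are in the Trichoderma one, of which 294 have none. Salmon divides reads between near-identical genes, so values of close paralogs (CYP71A12 and CYP71A13, the LHCB1, PHT1, AMT1 and HSP17 families, VSP1 and VSP2, PP2-B genes) are uncertain. The kit does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart.

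Gene names came from the TAIR10.1 RefSeq table, matched by locus for 32072 of the Arabidopsis identifiers, of which 10793 had a symbol of their own. None of its coordinates are printed, because the build of the counts is not named. Fungal identifiers are given as in the table, which pairs them with no names. At most 2 higher and 2 lower are named per comparison, besides a few said to be chosen after their values were seen.

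Group comparisons used edgeR 4.0.16 in R 4.3.3, with TMM normalisation, the filterByExpr filter over the 6 groups of an organism, robust quasi-likelihood fits and F tests. The prior count was 0.125, and p-values were adjusted by Benjamini-Hochberg with calls at an adjusted p under 0.05. All libraries of an organism shared 1 fit, with 12 residual degrees of freedom for Arabidopsis and 5 for Trichoderma. The filter left 20006 Arabidopsis and 9931 Trichoderma genes, and the common biological coefficient of variation was 14.8 and 30.7%. The standard error of a log2 fold change was its size divided by the root of its F statistic. CPM are counts scaled by the TMM library size, per 1e6, and the single wild-type library alone was assumed to vary like the other groups. For a group at 0 counts the fold is a lower bound against 3 counts over the group, and floors cover counting error only.

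The 24 gene lists hold 434 members (433 genes, 433 members in the table). They cover jasmonate, salicylic acid, ethylene, auxin, cytokinin, abscisic acid, camalexin, indole and aliphatic glucosinolates, pattern-triggered immunity, reactive oxygen, hypoxia, phosphate, iron, nitrogen, sugar transport, Casparian strip and suberin, phenylpropanoids, flavonoids, root hairs, cell division, green shoot tissue, heat shock and reference genes. The lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. No list was called with an estimated correlation in any of the 9 comparisons.

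Groups, tests, lists, alternatives and the naming rule were chosen before the data were examined. The rule took the 5 genes with the largest positive and the 5 with the largest negative log2 fold change among called genes whose groups did not overlap, with a symbol and a mean log2 CPM of at least 1. It added up to 3 called members of each list by smallest adjusted p, and the fixed genes PR1, PDF1.2A, VSP2, PAD3, CYP71A12, MYB51, RBOHD, ADH1, IRT1 and WRKY33. Not all are printed. With 3 libraries against 3, chance gives non-overlapping groups for 10% of genes. PR1 (AT2G14610), with 6 counts in 18 libraries, and PDF1.2A (AT5G44420), with 0, were not tested.

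The procedure was tested on simulated counts with 200 changed genes. For roots with the wild type against roots alone at 3 dpi, over 20006 genes, it recovered 16, 62, 98 and 92% of changes of 1.5-, 2-, 4- and 8-fold, and 4.2% of calls were false. For the mutant against the wild type with the plant at 3 dpi in the fungus, over 9931 genes, it recovered 0, 0, 66 and 84%, and 10.7% of calls were false. Among calls for the wild-type fungus at 5 dpi against its single library, 12.2% were false in simulated data.

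Alternatives were RLE normalisation, DESeq2 1.42.0, no filter on low counts, a 2-fold minimum, the replicate number as a block, each library left out in turn, only the libraries compared, and the Arabidopsis tests without organelle genes. Thinning all root libraries to 1954260 counts and fitting the fungus without a library were added after the data were seen. Within groups no 2 libraries agreed within sampling noise, the chi-square per gene being 2.2 to 24.4 in roots and 10.7 to 45.8 in the fungus.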

Results

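The samples came from a dual RNA-seq study of the plant Arabidopsis thaliana and the soil fungus Trichoderma atroviride, which colonises roots and is used in biological control. Roots and mycelium were sequenced after growth together or apart, with either the wild-type fungus or a mutant that lacks noxR, the gene for a regulatory subunit of the fungal NADPH oxidases that produce reactive oxygen species. Spores were placed 5 cm from the seedlings, and samples were taken at 3 days post inoculation (dpi), before the partners touched, and at 5 dpi, after contact. There were 18 root libraries in 6 groups of 3, namely roots alone, roots with the wild type and roots with the mutant at each time. The 11 fungal libraries fell into 6 groups, with 2 libraries each for the mutant alone at 5 dpi and for either strain with the plant at 3 and 5 dpi, and 1 library for the wild type alone at 5 dpi. Root libraries held 1.95 to 16.0 M counts, and fungal libraries 0.893 to 12.7 M.

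The noxR gene itself was not analysed here, because the fungal gene identifiers carry no gene names in the sources used here, so that gene gives no check of the strain labels. Principal components of the root libraries put 59.5% of the variance on the first component and 8.1% on the second, and those of the fungal libraries 49.3% and 12.3%. Across genes, replicates of one group correlated at 0.942 to 0.986 in roots and at 0.899 to 0.952 in the fungus. All CPM values are means ± SD over the libraries of a group (n = 3 for roots), and log2 fold changes are given ± SE.

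The first question was how roots respond before contact, comparing roots with the wild-type fungus to roots alone at 3 dpi. Genes of nitrate reduction rose, while the whole nitrogen list had 3 higher and 1 lower of 18, and 4 and 3 adjusted over the list alone. Its median log2 fold change was -0.10 and camera's direction was up (adjusted p = 0.278, and adjusted p = 0.786 with an estimated correlation). NIA1 (AT1G77760), a nitrate reductase, rose from 27.7 ± 1.22 to 294 ± 77.5 CPM (log2 fold change 3.41 ± 0.32, adjusted p = 8.76e-06). NIA2 (AT1G37130), the other nitrate reductase, rose from 274 ± 52 to 769 ± 172 CPM (log2 fold change 1.49 ± 0.19, adjusted p = 0.000103). The nitrite reductase gene NIR1 (AT2G15620) (1.11 ± 0.18) was higher as well. BCAT4 (AT3G19710) (2.97 ± 0.39), which starts the methionine chain elongation of aliphatic glucosinolates, rose, and CYP79F2 (AT1G16400) (2.16 ± 0.28) and IMD1 (AT5G14200) (1.75 ± 0.28) of the same pathway rose with it. PGB1 (AT2G16060), a phytoglobin of the hypoxia response that scavenges nitric oxide, rose from 5.09 ± 0.981 to 36.9 ± 12.6 CPM. The auxin-conjugating enzyme gene GH3.3 (AT2G23170) (1.25 ± 0.24) and the cell wall peroxidase gene PRX37 (AT4G08770) (1.19 ± 0.21) also rose. In the opposite direction, SWEET12 (AT5G23660), a sucrose exporter, fell from 72.7 ± 27.1 to 14.7 ± 4.55 CPM (log2 fold change -2.26 ± 0.31, adjusted p = 0.000734), and its partner SWEET11 (AT3G48740) (-2.62 ± 0.40) fell too. The Casparian strip membrane protein genes CASP4 (AT5G06200) (-1.21 ± 0.17) and CASP5 (AT5G15290) (-1.67 ± 0.27) fell, as did CKX4 (AT4G29740) (-1.42 ± 0.26), a cytokinin oxidase gene. The whole Casparian strip and suberin list had 1 higher and 2 lower of 18, and 5 and 2 adjusted over the list alone. Its median log2 fold change was 0.28 and camera's direction was up (adjusted p = 0.463, and adjusted p = 0.786 with an estimated correlation).

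Of the 13 aliphatic glucosinolate genes tested, 10 were called higher and 0 lower, and 13 were higher when adjusted over the list alone. The camera test of this list gave an adjusted p = 2.11e-21, and adjusted p = 0.117 with an estimated correlation. Hypoxia response genes were higher in 5 of 19 and lower in 0, with 12 higher when adjusted over the list alone (camera adjusted p = 3.37e-09, and adjusted p = 0.219 with an estimated correlation). Phenylpropanoid and lignin genes were higher in 4 of 17, with 6 adjusted over the list alone (adjusted p = 8.81e-05, and adjusted p = 0.279 with an estimated correlation). In the iron deficiency list 1 gene was higher and 5 lower of 22, with 2 and 9 adjusted over the list alone (adjusted p = 0.00951, and adjusted p = 0.279 with an estimated correlation). Sugar transport and cleavage genes were higher in 2 and lower in 3 of 14, and 3 and 5 adjusted over the list alone (adjusted p = 0.0268, and adjusted p = 0.279 with an estimated correlation). No member of the jasmonate list passed over all genes in edgeR's shared fit, of 17 tested, and 0 passed adjusted over the list alone, but VSP2 (AT5G24770) passed in a fit on the 6 libraries compared (-1.94, adjusted p = 0.0426, against adjusted p = 0.151). Outside the list the jasmonate-responsive TAT3 (AT2G24850) was called higher (4.10 ± 1.16, adjusted p = 0.0484) on 22 counts against 1, and lost its call without any 1 of the 6 libraries (adjusted p = 0.0773 to 0.185). In the salicylic acid list 0 were higher and 1 was lower of 15, and 0 and 2 adjusted over the list alone. Its median log2 fold change was 0.13, while its mean was -0.34 and camera's direction was down (adjusted p = 0.349, and adjusted p = 0.786 with an estimated correlation). Markers of green shoot tissue shifted in the same libraries, with 3 of 23 lower over all genes and 12 adjusted over the list alone (adjusted p = 1.33e-10, and adjusted p = 0.279 with an estimated correlation). Their share of counts was 0.209, 0.349 and 0.205% in the 3 libraries of roots alone and 0.127, 0.142 and 0.0488% with the wild type.

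Over all genes, 984 of 20006 tested were called at 3 dpi, 459 higher and 525 lower. Leaving out 1 library lowered this count by more than 1.5 times for the wild-type-exposed replicates 1 and 2, to 388 and 612, and for replicates 2 and 3 of roots alone, to 448 and 581. Of the 53 genes called that the naming rule took, 24 stayed called without any 1 library. Every gene given with a value in the first paragraph on this comparison was among these.

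Roots with the noxR mutant at 3 dpi were compared with the same controls to ask whether the mutant elicits the response before contact. NIA1 rose from 27.7 ± 1.22 to 538 ± 36.9 CPM (log2 fold change 4.27 ± 0.33, adjusted p = 3.6e-07). PGB1 rose from 5.09 ± 0.981 to 78.3 ± 26.9 CPM (log2 fold change 3.97 ± 0.47, adjusted p = 9.03e-05). GAD4 (AT2G02010), a glutamate decarboxylase, rose from 0.338 ± 0.128 to 26.2 ± 12.7 CPM (log2 fold change 6.14 ± 0.80, adjusted p = 0.000225). ADH1 (AT1G77120), the alcohol dehydrogenase of fermentation, rose from 11.3 ± 2.53 to 84.2 ± 25.3 CPM (log2 fold change 2.90 ± 0.40, adjusted p = 0.000289). PAD3 (AT3G26830), the last enzyme in the synthesis of camalexin, the main phytoalexin of Arabidopsis, rose from 4.71 ± 1.37 to 37.7 ± 9.4 CPM (log2 fold change 2.92 ± 0.40, adjusted p = 0.000242). BCAT4 (3.74 ± 0.40), GH3.3 (2.51 ± 0.24) and NAS2 (AT5G56080) (2.57 ± 0.37), a nicotianamine synthase gene, were higher too. PP2-B8 (AT2G02340), which had no count in roots alone at 3 dpi, reached 2.23 ± 0.983 CPM, at least 22.1-fold higher against a floor of 3 counts over the group. TIP2;3 (AT5G47450), a tonoplast aquaporin, fell from 167 ± 41.1 to 10.2 ± 2.47 CPM (log2 fold change -4.02 ± 0.28, adjusted p = 1.05e-07). SWEET12 (-3.27 ± 0.36), SWEET11 (-3.06 ± 0.46), CASP4 (-2.14 ± 0.20), CASP5 (-2.72 ± 0.33) and CKX4 (-2.53 ± 0.30) fell, as did the iron uptake regulator FIT (AT2G28160) (-0.94 ± 0.18).

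Aliphatic glucosinolate genes were higher in 11 of 13, and in 13 adjusted over the list alone (camera adjusted p = 5.77e-21, and adjusted p = 0.0624 with an estimated correlation). In the hypoxia list 14 of 19 were higher and 0 lower, with 14 adjusted over the list alone, among them ACO1 (AT2G19590) at 1.21 ± 0.19 (adjusted p = 3.08e-15, and adjusted p = 0.0624 with an estimated correlation). Ethylene synthesis and response genes were higher in 7 and lower in 1 of 17, and 9 and 1 adjusted over the list alone (adjusted p = 0.00161, and adjusted p = 0.2 with an estimated correlation). The camalexin list had 5 of 16 higher and 8 adjusted over the list alone (adjusted p = 1.31e-05, and adjusted p = 0.327 with an estimated correlation). Phenylpropanoid and lignin genes were higher in 8 of 17, and 8 adjusted over the list alone (adjusted p = 9.31e-05, and adjusted p = 0.263 with an estimated correlation). Iron deficiency genes were higher in 2 and lower in 6 of 22, and 4 and 7 adjusted over the list alone. Camera gave the iron list adjusted p = 0.0871, and adjusted p = 0.388 with an estimated correlation. Of 18 Casparian strip and suberin genes, 7 were higher and 5 lower, and 11 and 5 adjusted over the list alone (adjusted p = 0.0871, and adjusted p = 0.508 with an estimated correlation). The genes that rose included FAR5 (AT3G44550), a fatty acyl reductase of suberin, from 31.6 ± 4.56 to 66.7 ± 8.35 CPM, while those that fell included the Casparian strip genes above. Green shoot markers were lower in 17 of 23, and 23 adjusted over the list alone (adjusted p = 2.37e-14, and adjusted p = 0.23 with an estimated correlation), and their share of counts was 0.0647, 0.0738 and 0.0581%.

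In total 2489 genes were called, 1229 higher and 1260 lower, and leaving out replicate 1 of the mutant-exposed roots gave 1284, replicate 2 of roots alone 1406. Of the 74 genes called that the naming rule took, 54 stayed called without any 1 library. The iron transporter IRT1 (AT4G19690) (-4.07 ± 1.06, adjusted p = 0.0243) lost its call without replicate 1 or 2 of the mutant-exposed roots (adjusted p = 0.168 and 0.0824) or replicate 1 of roots alone (adjusted p = 0.0721), and its log2 fold change moved to -3.26 and -4.94 without replicates 1 and 3 of the mutant-exposed roots. The ferric reductase FRO2 (AT1G01580) (-4.27 ± 0.86, adjusted p = 0.0052) lost its call without replicate 1 of the mutant-exposed roots (adjusted p = 0.0546).

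**Figure D1:**
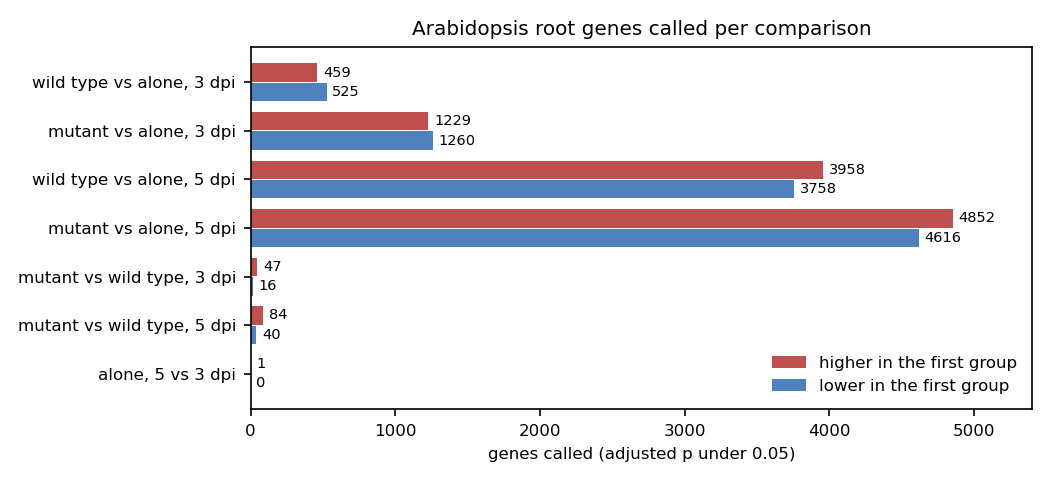
Number of Arabidopsis root genes called by edgeR (x axis, genes at an adjusted p under 0.05) in each of 7 comparisons (y axis), with bars for genes higher (red) and lower (blue) in the first group named. Counts run from 1 in roots alone over time to 4852 higher and 4616 lower with the mutant at 5 dpi.

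After contact, at 5 dpi, roots with the wild type differed from roots alone in 7716 genes, 3958 higher and 3758 lower. CYP71A12 (AT2G30750), a cytochrome P450 that makes camalexin and related indolic compounds and whose counts may be shared with the near-identical CYP71A13, rose from 44.6 ± 4.47 to 725 ± 71.5 CPM (log2 fold change 4.02 ± 0.36, adjusted p = 3.86e-07). PAD3 rose from 6.53 ± 1.42 to 386 ± 139 CPM (log2 fold change 5.91 ± 0.41, adjusted p = 3.45e-08). NIA1 rose from 26.5 ± 15.1 to 1810 ± 17 CPM (log2 fold change 6.09 ± 0.35, adjusted p = 1.63e-09). GH3.3 rose from 7.55 ± 3.04 to 631 ± 135 CPM (log2 fold change 6.29 ± 0.24, adjusted p = 1.76e-12). RBOHD (AT5G47910), the main NADPH oxidase of immune signalling in the plant, rose from 58 ± 6.97 to 261 ± 27.3 CPM (log2 fold change 2.16 ± 0.15, adjusted p = 2.03e-09). WRKY33 (AT2G38470) and MYB51 (AT1G18570), transcription factors of camalexin and of indole glucosinolate synthesis, rose by 1.52 ± 0.25 and 2.08 ± 0.24 on the log2 scale. The heat shock gene HSP18.2 (AT5G59720) (5.11 ± 0.39), the ethylene synthesis gene ACS6 (AT4G11280) (3.69 ± 0.33), the stress zinc finger gene ZAT12 (AT5G59820) (3.22 ± 0.27), the jasmonate repressor gene JAZ10 (AT5G13220) (3.93 ± 0.37) and the hexose transporter gene STP13 (AT5G26340) (2.71 ± 0.28) rose. TIP2;3 fell from 136 ± 42.6 to 2.11 ± 1.04 CPM (log2 fold change -5.84 ± 0.33, adjusted p = 1.05e-09). FIT fell from 85.8 ± 17 to 15.3 ± 2.91 CPM (log2 fold change -2.46 ± 0.19, adjusted p = 9.05e-09). CASP4 fell from 22 ± 4.39 to 3.75 ± 0.97 CPM (log2 fold change -2.46 ± 0.20, adjusted p = 1.3e-08). PER64 (AT5G42180) (-2.11 ± 0.19), a peroxidase of the Casparian strip, EXPA7 (AT1G12560) (-1.56 ± 0.23), an expansin of root hairs, and IPT5 (AT5G19040) (-1.75 ± 0.19), a cytokinin synthesis gene, were lower.

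Group by group, 14 of 16 camalexin genes were higher and 0 lower, and 14 adjusted over the list alone (camera adjusted p = 9.63e-17, and adjusted p = 0.0613 with an estimated correlation). All 13 aliphatic glucosinolate genes tested and all 9 heat shock genes tested were higher, with the same counts adjusted over the list alone (adjusted p = 9.4e-13 and 9.2e-12, and adjusted p = 0.0613 with an estimated correlation for each). Jasmonate genes were higher in 12 and lower in 1 of 17, as when adjusted over the list alone (adjusted p = 9.91e-08, and adjusted p = 0.0613 with an estimated correlation). Salicylic acid genes were higher in 10 of 15, including EDS5 (AT4G39030) (1.44 ± 0.14) and PAD4 (AT3G52430) (1.36 ± 0.11), and 10 adjusted over the list alone (adjusted p = 1.01e-05, and adjusted p = 0.135 with an estimated correlation). Indole glucosinolate genes were higher in 11 of 14 and 11 adjusted over the list alone (adjusted p = 6.11e-06, and adjusted p = 0.0613 with an estimated correlation). Of 20 auxin genes, 13 were higher and 2 lower, and 15 and 2 adjusted over the list alone (adjusted p = 1.22e-06, and adjusted p = 0.0613 with an estimated correlation). The pattern-triggered immunity list had 15 higher and 3 lower of 24, as adjusted over the list alone (adjusted p = 1.23e-05, and adjusted p = 0.224 with an estimated correlation). The list of reactive oxygen production and scavenging had 14 higher and 3 lower of 22, as adjusted over the list alone (adjusted p = 2.16e-05, and adjusted p = 0.0613 with an estimated correlation). Abscisic acid genes were higher in 12 and lower in 3 of 17, and 13 and 3 adjusted over the list alone (adjusted p = 0.00219, and adjusted p = 0.333 with an estimated correlation). Casparian strip and suberin genes went both ways, with 6 higher and 7 lower of 18, as adjusted over the list alone. Their median log2 fold change was 0.15, while their mean was -0.16 and camera's direction was down. Iron deficiency genes had 5 higher and 7 lower of 22, as adjusted over the list alone. Camera gave these 2 lists adjusted p = 0.482 and 0.562, and adjusted p = 0.732 for each with an estimated correlation.

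Lower groups at 5 dpi were the root hair genes, with 2 higher and 8 lower of 14, and 2 and 9 adjusted over the list alone (camera adjusted p = 0.00665, and adjusted p = 0.489 with an estimated correlation). Cytokinin genes were higher in 1 and lower in 7 of 14, and 1 and 8 adjusted over the list alone (adjusted p = 0.00673, and adjusted p = 0.136 with an estimated correlation). Green shoot markers were lower in 15 of 23, and 17 adjusted over the list alone (adjusted p = 0.00153, and adjusted p = 0.563 with an estimated correlation), and their share of counts was 0.0444, 0.0463 and 0.0459% against 0.228, 0.0833 and 0.0975% in roots alone. Among 5 reference genes, ACT2 (AT3G18780), an actin, was lower (-0.92 ± 0.12, adjusted p = 5.26e-06), and UBQ10 (AT4G05320), a polyubiquitin, was higher (0.49 ± 0.19, adjusted p = 0.0447). UBQ10 lost its call without wild-type-exposed replicate 1, 2 or 3 (adjusted p = 0.0732, 0.0781 and 0.126) or replicate 2 or 3 of roots alone (adjusted p = 0.0984 and 0.174). Adjusted over the list alone 1 was higher and 1 lower (camera adjusted p = 0.482, and adjusted p = 0.732 with an estimated correlation). Leaving out 1 library kept the total between 6507 and 6862.

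With the mutant at 5 dpi, 9468 genes were called, 4852 higher and 4616 lower. CYP71A12 rose from 44.6 ± 4.47 to 1500 ± 508 CPM (log2 fold change 5.08 ± 0.38, adjusted p = 2.62e-08). PAD3 rose from 6.53 ± 1.42 to 795 ± 406 CPM (log2 fold change 6.96 ± 0.42, adjusted p = 4.47e-09). JAZ10 rose from 0.665 ± 0.0832 to 36.7 ± 16 CPM (log2 fold change 5.69 ± 0.35, adjusted p = 2.03e-10). ERF2 (AT5G47220) (5.39 ± 0.34), an ethylene-responsive transcription factor, rose. CCR2 (AT1G80820), a cinnamoyl-CoA reductase, rose from 12.5 ± 1.59 to 137 ± 24.9 CPM (log2 fold change 3.43 ± 0.22, adjusted p = 4.85e-10). ADH1 rose from 12 ± 2.89 to 234 ± 73.5 CPM (log2 fold change 4.26 ± 0.41, adjusted p = 8.12e-07). TIP2;3 fell from 136 ± 42.6 to 1.3 ± 0.894 CPM (log2 fold change -6.72 ± 0.38, adjusted p = 4.88e-10). FIT fell from 85.8 ± 17 to 6.49 ± 2.59 CPM (log2 fold change -3.53 ± 0.22, adjusted p = 2.13e-10). CASP4 fell from 22 ± 4.39 to 1.61 ± 0.046 CPM (log2 fold change -3.78 ± 0.25, adjusted p = 4.56e-10). scpl18 (AT1G33540), a serine carboxypeptidase-like gene at 0 counts in all 3 mutant-exposed libraries, was at least 21.7-fold lower against a floor of 3 counts over the group. The actin ACT2 was lower here too (-1.24 ± 0.12, adjusted p = 7.78e-08). Among the lists, 15 of 16 camalexin genes, 13 of 17 jasmonate genes, 11 of 15 salicylic acid genes and 18 of 24 immunity genes were higher, and 15, 14, 11 and 19 adjusted over the list alone. Camera gave adjusted p = 1.7e-18, 1.33e-10, 7.31e-08 and 1.19e-08 for these lists, and adjusted p = 0.0619, 0.0619, 0.0765 and 0.0988 with an estimated correlation. Jasmonate genes were lower in 1, salicylic acid genes in 0 and immunity genes in 2. Casparian strip and suberin genes were higher in 5 and lower in 8 of 18, as adjusted over the list alone. Iron deficiency genes were higher in 5 and lower in 10 of 22, and 6 and 11 adjusted over the list alone. Camera gave these lists adjusted p = 0.148 and 0.341, and adjusted p = 0.565 and 0.583 with an estimated correlation. Green shoot markers were lower in 15 of 23 and 15 adjusted over the list alone (adjusted p = 0.00205, and adjusted p = 0.571 with an estimated correlation), at 0.0479, 0.028 and 0.0352% of counts. Without any 1 library the total stayed between 8638 and 8834.

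**Figure D2:**
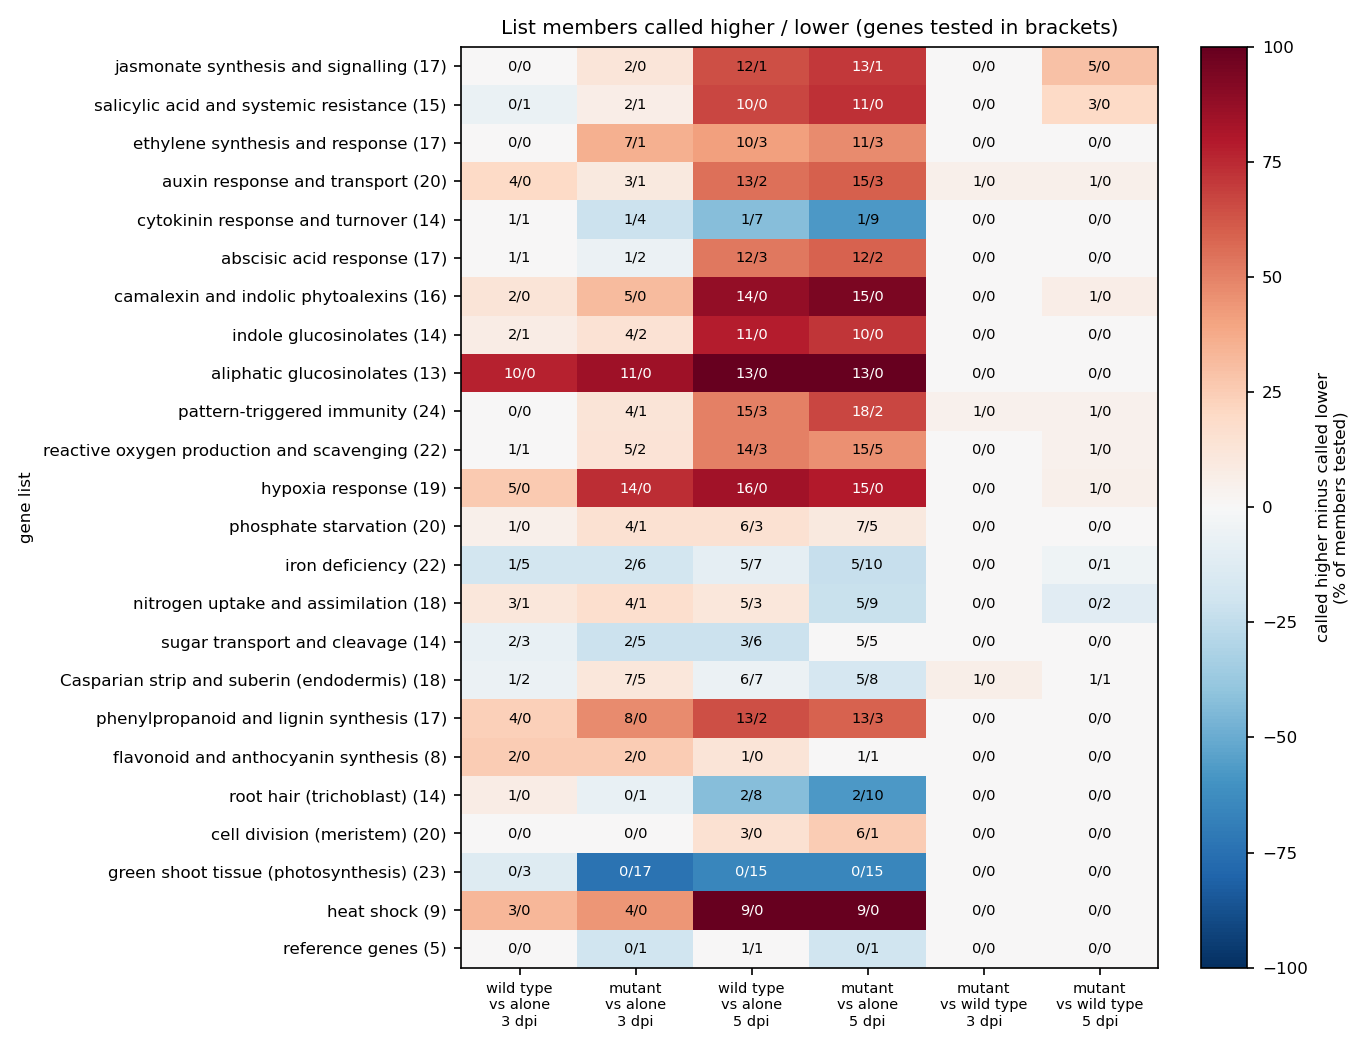
Members of each of 24 gene lists (y axis, genes tested in brackets) called higher / lower in 6 root comparisons (x axis), with colour for the number higher minus the number lower as a percent of the members tested. Aliphatic glucosinolate genes were higher in 10, 11, 13 and 13 of 13 against roots alone, and jasmonate genes in 5 of 17 between strains at 5 dpi.

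How far the strains shared their calls was measured on the genes called with each strain at the same time. At 3 dpi 395 genes were higher with both strains, 433 were lower with both and 0 went opposite ways, which is 84.1% of the wild-type calls. Independent lists would share 28 and 33. At 5 dpi the counts were 3636, 3427 and 0, or 91.5% of the wild-type calls, where independent lists would share 960 and 867. Both comparisons use the same control libraries, and 20 simulations of unchanged groups against those controls shared at most 0 calls at 3 dpi and 1 at 5 dpi. Fold changes correlated across genes at 0.771 and 0.953, where simulation gave 0.453 at each time. The covariances were 0.32 and 1.46 against simulated 0.0453 and 0.0478, differences of 0.275 and 1.41. The shares of genes with the same sign were 76.3 and 88.9% against 65 and 65.3%. The simulations hold no effects and the independent lists no shared controls. The 3 controls per time were not split, since no split leaves 2 in each part, so part of the excess may come from the shared controls.

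The strains were then compared directly, which tests the difference between their effects because the control cancels. At 3 dpi PER5 (AT1G14550), a peroxidase gene from the immunity list, was higher with the mutant, at 11.3 ± 3.63 against 1.57 ± 0.361 CPM (log2 fold change 2.98 ± 0.36, adjusted p = 0.000501), and stayed called without any 1 library. GH3.3 was also higher, at 36.2 ± 9.62 against 14.9 ± 1.34 CPM (log2 fold change 1.26 ± 0.22, adjusted p = 0.0152), and lost its call without mutant-exposed replicate 2 (adjusted p = 0.124) or wild-type-exposed replicate 1 or 3 (adjusted p = 0.17 and 0.0678). The multicopper oxidase-like gene sks15 (AT4G37160) was lower, at 3.89 ± 1.01 against 15.5 ± 2.76 CPM (log2 fold change -2.13 ± 0.34, adjusted p = 0.0081), and lost its call without replicate 1 of the mutant-exposed roots (adjusted p = 0.165). PAD3 (1.16 ± 0.37, adjusted p = 0.287), CYP71A12 (1.57 ± 0.37, adjusted p = 0.096) and ADH1 (0.90 ± 0.36, adjusted p = 0.473) did not pass in the shared fit. In a fit on the 6 libraries compared PAD3 (1.18, adjusted p = 0.0044) and CYP71A12 (1.58, adjusted p = 0.00119) passed, and CYP71A12 also passed in DESeq2 (adjusted p = 0.0123) and after thinning (adjusted p = 0.0283). Over all genes 63 were called, 47 higher and 16 lower with the mutant, and 171 by DESeq2. Without mutant-exposed replicate 1 or 2 there were 10 and 16, and without wild-type-exposed replicate 1 or 3 there were 9 and 21. Of the 13 named genes called, 1 stayed called without any 1 library.

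By list at 3 dpi, the camalexin genes stood at 0 called of 16 in edgeR over all genes and 5 higher adjusted over the list alone (camera adjusted p = 2.83e-08, and adjusted p = 0.209 with an estimated correlation). Hypoxia genes had 0 called of 19 and 2 higher adjusted over the list alone (adjusted p = 1.49e-07, and adjusted p = 0.209 with an estimated correlation). Root hair genes had 0 called of 14 and 1 lower adjusted over the list alone (adjusted p = 9.26e-08, and adjusted p = 0.209 with an estimated correlation). Green shoot markers had 0 called of 23 and 0 adjusted over the list alone, with a median log2 fold change of -0.80 (adjusted p = 9.7e-05, and adjusted p = 0.475 with an estimated correlation). In the whole comparison 1768 genes had an unadjusted p under 0.05.

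At 5 dpi 5 of 17 jasmonate genes were called higher with the mutant than with the wild type, and 12 were not called. JAZ10 stood at 36.7 ± 16 against 10.1 ± 2.88 CPM (log2 fold change 1.75 ± 0.25, adjusted p = 0.00392). Outside the list, TAT3 (AT2G24850), a jasmonate-responsive tyrosine aminotransferase, stood at 33.6 ± 13.6 against 4.36 ± 2.63 CPM (log2 fold change 2.71 ± 0.38, adjusted p = 0.00392). Of the salicylic acid genes, EDS5, a transporter, stood at 129 ± 27.1 against 69.5 ± 2.42 CPM (log2 fold change 0.89 ± 0.13, adjusted p = 0.00627). ICS1 (AT1G74710), isochorismate synthase, stood at 34.9 ± 14.5 against 15.3 ± 3.77 CPM (log2 fold change 1.25 ± 0.23, adjusted p = 0.0209). ICS1 lost its call without mutant-exposed replicate 2 (adjusted p = 0.0863) or wild-type-exposed replicate 1 or 2 (adjusted p = 0.15 and 0.112). FIT was lower, at 6.49 ± 2.59 against 15.3 ± 2.91 CPM (log2 fold change -1.08 ± 0.23, adjusted p = 0.0433), and lost its call without mutant-exposed replicate 2 or 3 (adjusted p = 0.167 and 0.0761) or wild-type-exposed replicate 1 or 2 (adjusted p = 0.12 and 0.192). VSP2 (AT5G24770) (1.49 ± 0.46, adjusted p = 0.14), CYP71A12 (1.05 ± 0.32, adjusted p = 0.139) and RBOHD (0.52 ± 0.14, adjusted p = 0.0951) did not pass in the shared fit. VSP2 passed without mutant-exposed replicate 1 (1.85, adjusted p = 0.0411), RBOHD in DESeq2 (adjusted p = 0.0312) and CYP71A12 after thinning (adjusted p = 0.0405). Jasmonate genes were higher in 5 and lower in 0 of 17, and 12 and 1 adjusted over the list alone (camera adjusted p = 3.67e-13, and adjusted p = 0.0827 with an estimated correlation). Salicylic acid genes were higher in 3 of 15, and 8 higher and 1 lower adjusted over the list alone (adjusted p = 4.83e-09, and adjusted p = 0.15 with an estimated correlation). Camalexin genes were higher in 1 of 16, and in 14 adjusted over the list alone. Pattern-triggered immunity genes were higher in 1 of 24, and in 15 adjusted over the list alone. Camera gave these lists adjusted p = 3.67e-13 and 9.81e-13, and adjusted p = 0.15 for each with an estimated correlation. Nitrogen uptake and assimilation genes were lower in 2 of 18, and 6 adjusted over the list alone (adjusted p = 2.95e-05, and adjusted p = 0.211 with an estimated correlation). Green shoot markers had 0 called of 23 in edgeR and 0 adjusted over the list alone (adjusted p = 0.195, and adjusted p = 0.822 with an estimated correlation).

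In all 124 genes were called between the strains at 5 dpi, 84 higher and 40 lower with the mutant, with 2664 at an unadjusted p under 0.05 and 344 called by DESeq2. Without mutant-exposed replicate 1 there were 619, without replicate 2 there were 30 and without replicate 3 there were 74, and without wild-type-exposed replicates 1 and 2 there were 25 and 13. JAZ10, TAT3, EDS5 and scpl30 were the 4 of 24 named genes that stayed called without any 1 library, and a fit on the 6 libraries compared called 0 genes.

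**Figure D3:**
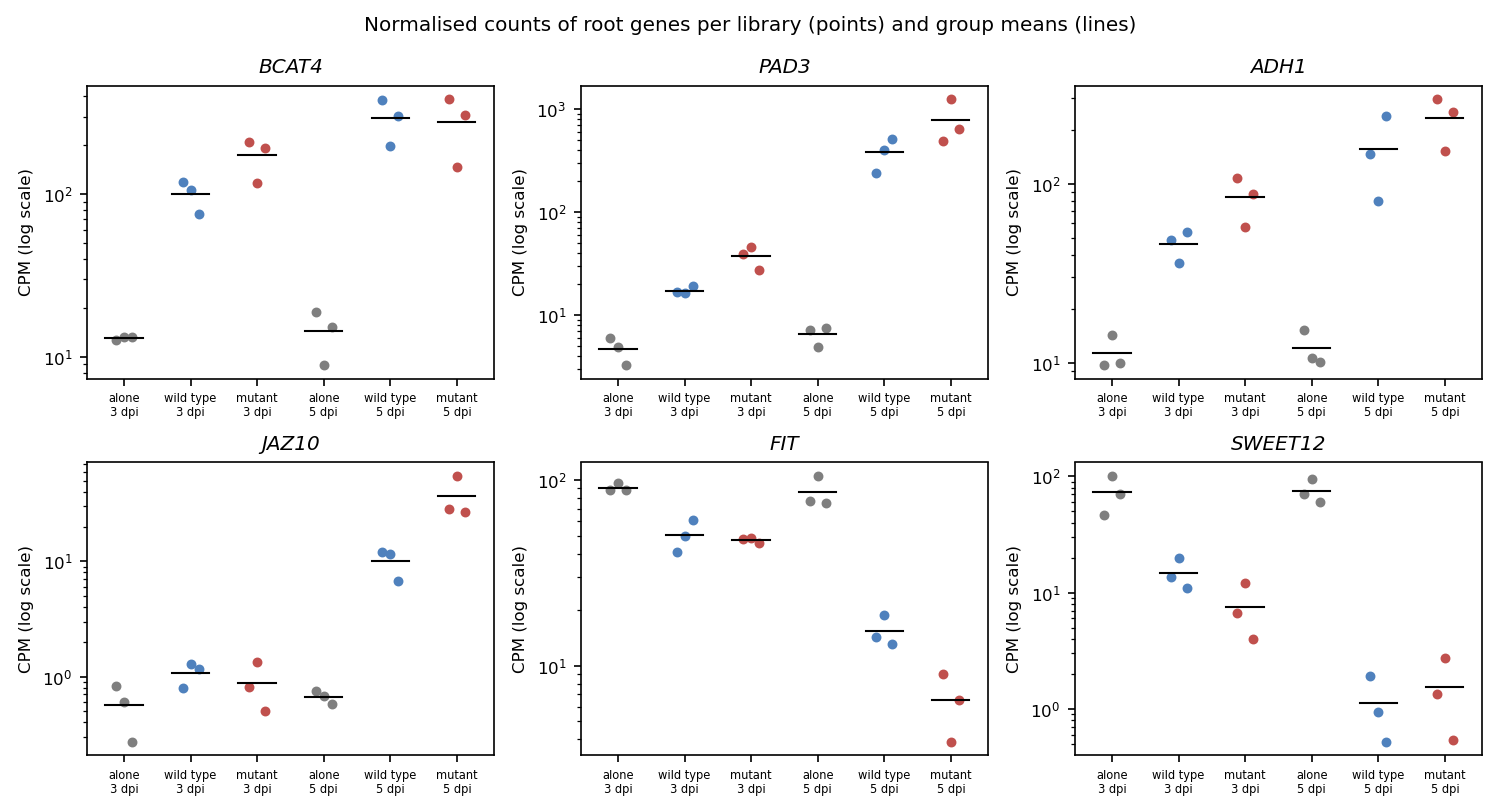
Normalised CPM (y axes, log scale) of BCAT4, PAD3, ADH1, JAZ10, FIT and SWEET12 in the 18 root libraries (points) by group and time (x axes), with group means as lines. JAZ10 had a mean of 36.7 CPM with the mutant and 10.1 CPM with the wild type at 5 dpi, against 0.665 CPM in roots alone.

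Whether the response to the wild type differed between times was tested with an interaction term, the response at 5 dpi minus that at 3 dpi. GH3.3 had the larger response at 5 dpi, by 5.04 ± 0.33, adjusted p = 2.86e-08, and so had the camalexin gene CYP71A12, by 4.51 ± 0.50, adjusted p = 3.71e-05 (3.74 without replicate 1 of roots alone at 3 dpi), and RBOHD, by 1.91 ± 0.21, adjusted p = 9.17e-06. PBS3 (AT5G13320), which makes a salicylic acid precursor, differed by 6.23 ± 0.95, adjusted p = 0.000579, VSP1 (AT5G24780), a jasmonate-responsive storage protein gene whose counts may be shared with VSP2, by 3.37 ± 0.45, adjusted p = 0.000116, and FIT by -1.58 ± 0.26, adjusted p = 0.000341. SKOR (AT3G02850), a potassium channel that loads the xylem, differed by -3.87 ± 0.40, adjusted p = 6.08e-06. In total 2801 genes differed, 1562 upward and 1239 downward, and 2107 to 2609 without any 1 library. Camalexin genes differed upward in 13 of 16, and in 14 adjusted over the list alone (camera adjusted p = 9.77e-23, and adjusted p = 0.0635 with an estimated correlation). Aliphatic glucosinolate genes differed in 1 of 13, and in 1 adjusted over the list alone (adjusted p = 0.000414, and adjusted p = 0.332 with an estimated correlation). Root hair genes differed downward in 10 of 14, and 10 downward and 1 upward adjusted over the list alone (adjusted p = 4.24e-06, and adjusted p = 0.186 with an estimated correlation), and green shoot markers in 0 of 23 (adjusted p = 0.941, and adjusted p = 0.984 with an estimated correlation).

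For single genes the strain difference was not shown to change with time. The interaction of strain and time called 0 genes in edgeR, with 1110 at an unadjusted p under 0.05 and 41 called by DESeq2. Without wild-type-exposed replicate 1 at 5 dpi it called 5. Camera called some lists at its preset correlation. Nitrogen genes went downward, with 5 of 18 lower adjusted over the list alone (adjusted p = 3.88e-08, and adjusted p = 0.338 with an estimated correlation). Casparian strip and suberin genes went downward (adjusted p = 6.96e-07, and adjusted p = 0.288), and jasmonate genes upward (adjusted p = 0.000205, and adjusted p = 0.397).

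Roots alone, the background of these comparisons, differed in 1 gene between 5 and 3 dpi. AT3G10120, named here after its values were seen, rose from 0 counts to 2.04 ± 0.841 CPM (n = 3, adjusted p = 0.00501). There were 863 genes at an unadjusted p under 0.05, DESeq2 called 1, and leaving out 1 library gave 39 without replicate 1 and 0 without replicate 2 at 3 dpi, and 2 without replicate 1 at 5 dpi. Green shoot markers had 0 called of 23 in edgeR and 0 adjusted over the list alone, with a median log2 fold change of -0.81 (camera adjusted p = 6.89e-16, and adjusted p = 0.988 with an estimated correlation). The preset camera test also placed the camalexin list higher at 5 dpi (adjusted p = 0.00347) and the nitrogen list lower (adjusted p = 0.033). With an estimated correlation camera gave adjusted p = 0.989 for each. Their median log2 fold changes were 0.29 and -0.13, and no member of either was called.

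In the fungus, the mutant grown with the plant at 5 dpi was compared with the mutant alone. The gene 80087 stood at 1050 and 509 CPM in the 2 libraries of the mutant alone and at 3.73 and 1 CPM with the plant, a log2 fold change of -8.42 ± 0.70 (adjusted p = 0.00396), and stayed called without any 1 library. In the wild type 80087 stood at 3.22 CPM alone and at 0.651 to 2.78 CPM with the plant, so it was high only in the mutant alone. The gene 242992 stood at 69.9 and 44 CPM in the mutant alone and at 0 counts in the mutant with the plant. It was at least 195-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 0.032). Its adjusted p was 0.178 to 0.356 on leaving out any 1 of the 4 libraries. In all 6 genes were called, 0 higher and 6 lower, with 734 at an unadjusted p under 0.05 and 51 by DESeq2, 22 higher and 29 lower. Leaving out replicate 1 of the mutant alone gave 2 genes, and leaving out replicate 1 or 2 of the mutant with the plant gave 1.

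At 3 dpi the mutant with the plant differed from the mutant alone, which was sampled at 5 dpi, so that plant and time cannot be told apart. It differed in 1 gene, again 80087, at 2.25 and 3.41 CPM (log2 fold change -8.26 ± 0.73, adjusted p = 0.00746), with 545 genes at an unadjusted p under 0.05 and 42 called by DESeq2. That call was lost without either library of the mutant with the plant (adjusted p = 1 and 0.393).

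The wild-type fungus with the plant at 5 dpi differed from its single library alone in 0 genes by edgeR, with 241 at an unadjusted p under 0.05 and 1 called by DESeq2. Leaving out the library labelled wild type with the plant at 5 dpi, replicate 2, gave 6. At 3 dpi the wild type with the plant differed from the same library, of 5 dpi, in 166 genes, 7 higher and 159 lower. DESeq2 called 1252, 441 higher and 811 lower, and leaving out either 3 dpi library gave 0. As the library alone was sampled at 5 dpi, plant and time cannot be told apart in this comparison. The genes 289358 and 296913 were at 72.8 ± 40.1 and 53.5 ± 26.5 CPM (n = 2) with the plant at 3 dpi and at 0 counts alone, at least 324-fold and 238-fold higher. The genes 296847 and 150692 were at 0 counts in both libraries and at 49.3 and 14.3 CPM alone, at least 110-fold and 31.8-fold lower.

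Between the strains, the mutant with the plant at 3 dpi differed from the wild type with the plant in 969 genes, 556 higher and 413 lower, and DESeq2 called 1583, 884 higher and 699 lower. The genes 296847 and 150692 were at 0 counts with the wild type and at least 55.6-fold and 32.9-fold higher in the mutant, at 25.0 ± 6.41 and 14.8 ± 4.74 CPM (n = 2, edgeR adjusted p = 0.0323 for each). The genes 296913 and 289358 were at 0 counts in the mutant and at least 95.0-fold and 129-fold lower. Without replicate 1 or replicate 2 of the mutant, or without replicate 2 of the wild type, 0 genes were called, and without replicate 1 of the wild type 1137. At 5 dpi the strains with the plant differed in 0 genes by edgeR, with 493 at an unadjusted p under 0.05 and 2 called by DESeq2, and in 52 without the library labelled wild type replicate 2.

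Without the plant at 5 dpi the strains differed in 0 genes by edgeR, with 468 at an unadjusted p under 0.05 and 15 by DESeq2. From 3 to 5 dpi with the plant, the wild type differed in 0 genes, with 1896 at an unadjusted p under 0.05 and 532 by DESeq2. It differed in 881 genes without its 5 dpi replicate 1 and in 1 without its 5 dpi replicate 2. The mutant differed over time in 0 genes by edgeR, with 70 at an unadjusted p under 0.05 and 1 by DESeq2. The interaction of strain and plant at 5 dpi called 0 genes, with 227 at an unadjusted p under 0.05 and 6 by DESeq2. In simulated data a 4-fold change was recovered for 66% of genes between the strains at 3 dpi, for 54% in the mutant at 5 dpi and for 20% in the wild type at 5 dpi, and a 2-fold change for 0, 2 and 0%.

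Named after their values were seen, the genes 269934, 315943 and 93330 were under 1 CPM in all 6 mutant libraries and at 13 to 160 CPM in the other 4 libraries of the wild type. In the library labelled wild type with the plant at 5 dpi, replicate 2, each had 0 counts, where 3 counts amount to 2.99 CPM.

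**Figure D4:**
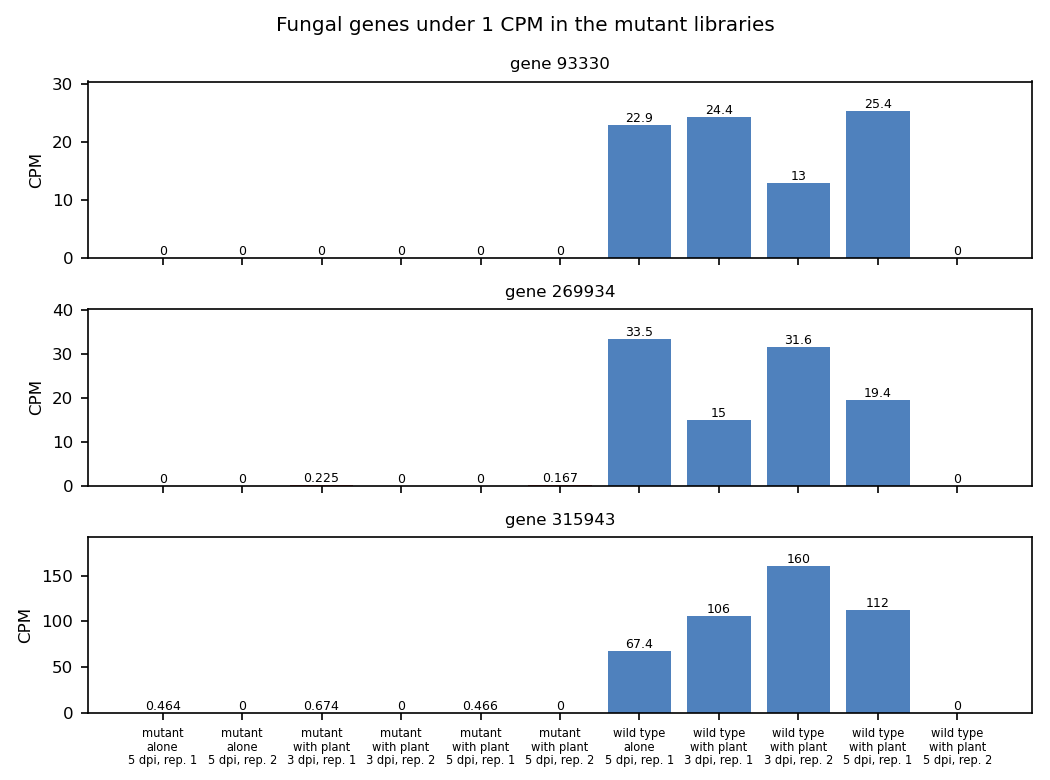
Normalised CPM (y axes) of the fungal genes 269934, 315943 and 93330 in each of the 11 fungal libraries (x axis), red for the mutant and blue for the wild type. The library labelled wild type with the plant at 5 dpi, replicate 2, stands at 0 for each gene, and the other 4 wild-type libraries stand between 13 and 160 CPM.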

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

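All tests given with a p-value or a count of genes in this part were planned; only the reading of the splits by whether the groups of a time stayed whole was chosen after the split counts were seen.

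The difference between the responses to the wild type at 5 and 3 dpi drew attention because the interaction test itself called 2801 genes. The largest upward differences among named genes were 7.40 on the log2 scale for GLIP1, a lipase of defence, 6.77 for SAG13, 6.58 for JRG21, 6.28 for AOX1D, an alternative oxidase, and 6.23 for PBS3. The largest downward differences were -3.49 for UMAMIT20, a transporter, -3.86 for sks15, -3.87 for SKOR, -6.37 for AGP30, an arabinogalactan protein, and -8.27 for GLR2.3, a glutamate receptor-like gene. GLIP1 lost its call without replicate 1 or 2 of roots alone at 3 dpi (adjusted p = 0.183 and 0.0539). JRG21 lost it without replicate 1 of roots alone at 3 dpi (adjusted p = 0.334) or replicate 1 of the wild-type-exposed roots at 3 dpi (adjusted p = 0.0725), and AOX1D without replicate 1 of roots alone at 3 dpi (adjusted p = 0.0687). SAG13 moved to 5.77 without replicate 1 of roots alone at 3 dpi and to 8.21 without replicate 1 of the wild-type-exposed roots at 3 dpi. Without replicate 1 of the wild-type-exposed roots at 5 dpi AGP30 moved to -8.11 and GLR2.3 to -10.02, and GLR2.3 moved to -7.47 without replicate 2 of roots alone at 5 dpi.

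Of 100 splits of the libraries within each time, the real one included, 9 gave at least 2801 genes. The highest other gave 7096. The 8 other splits were the 8 drawn that kept the groups of 5 dpi whole. Such splits carry the difference between those groups into the interaction, so this test did not exclude chance and cannot decide. Splits that mixed the groups at both times gave at most 0.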

How the results depend on the processing

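Thinning all root libraries, fitting without the library labelled wild type with the plant at 5 dpi, replicate 2, and the crossed block were chosen after the data were seen. Below, W, M and A stand for roots with the wild type, with the mutant and alone, and w, m, w-alone and m-alone for the fungal strains with the plant and alone, each with its time in dpi. Of the values that summarise a comparison, 64 moved by less than 1.5 times and 38 by more on leaving out 1 library, and under other settings 105 and 54. Both these values and those of single genes were counted once per comparison and setting, so the same gene counts many times. Genes not called that stayed so count as kept. For single genes, leaving out 1 library left 2656 values on their side of the threshold and took 367 below it and 3 above it. It changed the sign of 4. Other settings left 3218, took 186 below and 12 above. The cause was not tested unless given.

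Leaving out 1 library gave 388 to 801 genes for W3 against A3 (984), 1284 to 2049 for M3 against A3 (2489), 9 to 56 for M3 against W3 (63), 13 to 619 for M5 against W5 (124), 0 to 39 for A5 against A3 (1) and 0 to 5 for strain and time (0). In the fungus it gave 1 to 4 for m5 against m-alone (6), 0 to 2 for m3 against m-alone (1), 0 to 1137 for m3 against w3 (969), 0 to 52 for m5 against w5 (0), 0 to 0 for w3 against w-alone (166), 0 to 6 for w5 against w-alone (0) and 0 to 881 for w5 against w3 (0). Without a library a group of 2 has a lone sample, assumed to vary like the other groups. Changes of sign, in genes not called, were -0.11 for VSP2 in M3 against W3 without M3 replicate 1 (1.26 without W3 replicate 3) and 0.44 for IRT1 in M5 against W5 without W5 replicate 2 (-3.24 without W5 replicate 1). In W3 against A3 they were 0.08 for WRKY33 and 0.28 for CYP71A12 without A3 replicate 1 (-0.23 and -0.81 without A3 replicate 2).

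Among genes that passed only under another setting were CYP71A12 in M3 against A3 in DESeq2 (1.11, adjusted p = 0.0367), without A3 replicate 1 (1.85, adjusted p = 0.000215) and after thinning (1.15, adjusted p = 0.0169), WRKY33 in M3 against W3 on the libraries compared (0.51, adjusted p = 0.0331) and, in M5 against W5, PAD3 without M5 replicate 1 (1.31, adjusted p = 0.0293).

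A 2-fold minimum, which drops genes by construction, left 414, 1135, 3356 and 4672 genes for W3, M3, W5 and M5 against roots alone, 60 for M5 against W5, 1759 for time and the wild type, and 361 and 3146 shared calls in place of 828 and 7063. Thinning left 551 for W3, 1549 for M3, 23 for M3 against W3, 0 for A5 against A3, 1813 for time and the wild type, and 2 for strain and time. DESeq2 gave 171 for M3 against W3, 344 for M5 against W5 and 41 for strain and time. In the fungus it gave 1 for w5 and 1252 for w3 against w-alone, 51 for m5 and 42 for m3 against m-alone, 15 between the strains alone, 1583 for m3 against w3, 2 for m5 against w5, 532 for w5 against w3, 1 for m5 against m3 and 6 for strain and plant. Without a filter, strain and time gave 1 and w5 against w3 gave 5. A fit on only the libraries compared gave 221 for M3 against W3, 0 for M5 against W5, 0 for A5 against A3, 1472 for w3 against w-alone, 109 for m3 against m-alone and 191 between the strains alone. Without w5 replicate 2 in the shared fit, w3 against w-alone gave 1323 (391 higher, 932 lower), the strains alone 4 and m3 against w3 1596 (872 higher, 724 lower). With an estimated correlation camera called 0 lists in place of 11, 12, 17, 16, 14, 15, 3, 16 and 8.

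The replicate numbers were not taken to pair the libraries, since same-numbered libraries deviated together at -0.14 to 0.31 in roots and -0.2 to 0.31 in the fungus. As a hint from the data, 13 of 18 root and 8 of 10 fungal libraries correlated best with their own number in another group. In fungal groups of 2 the libraries deviate as mirror images, so both count the same outcome. In each root group replicate 1 was the deepest and 3 the shallowest. With the replicate number as a block, M3 against W3 gave 142, M5 against W5 291, strain and time 8, m5 against m-alone 1, the strains alone 1, m3 against w3 308 (198 higher, 110 lower) and w5 against w3 8, and VSP2 passed in M5 against W5 (1.53, adjusted p = 0.0358) and in W3 against A3 (-1.93, adjusted p = 0.048). The crossed block gave 0 for w5 against w-alone and for m5 against w5.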

Other observations

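The tests of the library labelled wild type with the plant at 5 dpi, replicate 2, and those of the root response score with either strain, thinning included, were chosen after these or related values were seen, while the splits were set before their result.

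Cell division genes of the root meristem were called in 0 of 20 with either strain and between the strains at 3 dpi in edgeR. Camera placed this list higher with the wild type (adjusted p = 0.0268, and adjusted p = 0.631 with an estimated correlation) and lower with the mutant than with the wild type (adjusted p = 0.0186, and adjusted p = 0.475). At 5 dpi 3 were higher with the wild type, and 1 adjusted over the list alone (camera adjusted p = 0.482, and adjusted p = 0.775 with an estimated correlation), among them CYCD3;1 (AT4G34160), a D-type cyclin (0.72 ± 0.20, adjusted p = 0.00738). Of the same list 6 were higher and 1 lower with the mutant, as adjusted over the list alone (camera adjusted p = 0.681, and adjusted p = 0.909 with an estimated correlation). Phosphate starvation genes went both ways at 5 dpi, with 6 higher and 3 lower of 20 with the wild type and 7 and 5 with the mutant, the same adjusted over the list alone, with camera adjusted p = 0.482 and 0.681, and adjusted p = 0.732 and 0.85 with an estimated correlation. Their medians of -0.04 and -0.08 were opposite in sign to their means of 0.28 and 0.27 and to camera's direction. NPC4 (AT3G03530), a phospholipase induced by phosphate shortage, rose with the wild type (2.61 ± 0.29, adjusted p = 7.19e-07). Flavonoid genes were higher in 2 of 8 with each strain at 3 dpi, and in 5 and 2 adjusted over the list alone (camera adjusted p = 8.81e-05 and 0.00345, and adjusted p = 0.279 and 0.388 with an estimated correlation). UGT78D1 (AT1G30530), a flavonol glycosyltransferase, rose with the wild type at 5 dpi (1.87 ± 0.29, adjusted p = 3.48e-05), where 1 of the 8 was higher. Nitrogen genes with the mutant at 5 dpi were higher in 5 and lower in 9 of 18, as adjusted over the list alone, with a median of -0.66 against a mean of 0.44 and an upward camera test (adjusted p = 0.794, and adjusted p = 0.938 with an estimated correlation). The green shoot markers fell at 5 dpi as described above, at 0.0444 to 0.0463% of counts with the wild type.

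The root response scored higher with the mutant at 3 dpi: over the 3356 genes changed at least 2-fold by the wild type at 5 dpi, the mean response score (log2) at 3 dpi was 0.83 ± 0.04 with the mutant and 0.44 ± 0.04 with the wild type (SD, n = 3, exact permutation p = 0.1, the smallest possible). Over the 414 genes of 3 dpi the scores at 5 dpi were 2.18 ± 0.11 and 2.09 ± 0.15 (exact p = 0.4). The sum of the differences at both times, 0.4 and 0.09, gave an exact permutation p = 0.02, which rests mainly on 3 dpi and does not show a difference at 5 dpi. A lower depth of the mutant-exposed libraries is argued against at 3 dpi, since thinning every library to one total left a difference of 0.33 (83.6%). Thinning lowered the 3 dpi scores with both strains, to 0.66 to 0.73 with the mutant and 0.34 to 0.38 with the wild type. The percent kept therefore reflects this lowering too. Depth stays open at 5 dpi, where 72.6% was kept of a difference of 0.09 that lay within the spread and so decides nothing. Roots with the mutant at 3 dpi may be further along the change that the wild type elicits at 5 dpi or respond more strongly in the same way. This stays open, since both ask for the correlation of r = 0.474 between that change and the strain difference, which largely restates the score. On means of log CPM it was 0.463 (highest other split 0.25, exact permutation p = 0.1). At 5 dpi the strain difference correlated with the response to the wild type at 3 dpi at r = 0.0412. On means of log CPM this was 0.0428 (highest other split 0.0959, exact permutation p = 0.6).

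In the library labelled wild type with the plant at 5 dpi, replicate 2, the genes 269934, 315943 and 93330 had 0 counts, while the mutant libraries held at most 3 counts of each (under 1 CPM). Loss of counts through low depth is argued against. Of 3951 other genes that lay at the same level in the 8 deeper libraries, 0 were at 0 counts here (0%). This does not cover other differences tied to the shallowest libraries, this one among them. The gene 55202 stood at 229 to 353 CPM in those and at 0 counts in the 8 deeper ones. The other shallow libraries were of the mutant, where the 3 genes were off, so such a difference was not tested. An effect of contact with the plant on the whole group is argued against by its other library, where genes chosen without either library of the group, which were the same 3, had a median of 25.4 CPM. A wrong label, with mutant RNA in this library, may explain the zeros, but 289358, at 0 counts in all 6 mutant libraries, stood at 72.7 CPM here. The gene 242992 stood at 31.9 CPM here, against 0 to 7.64 CPM in the mutant with the plant and 69.9 and 44 CPM in the mutant alone. In the other wild-type libraries it stood at 19.3 to 71.2 CPM. The gene 80087 stood at 0.995 CPM here, against 1 to 3.73 CPM in the mutant with the plant and 1050 and 509 CPM in the mutant alone. In the other wild-type libraries it stood at 0.651 to 3.22 CPM. For both genes this library thus lay within the range of the other wild-type libraries. The gene 296913 had 0 counts here, as in all mutant libraries and the group partner. The tables do not decide. A first form of this test, on the 3 genes alone, had gone for a wrong label before 289358 was looked at.

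The splits of the 6 libraries into 3 and 3 number 10 for each root comparison, the real one included, so their share cannot fall below 0.1 and only values are given. The real split gave the most genes, 1 split of 10, for the wild type at 3 dpi (984, highest other 0), the mutant at 3 dpi (2489, highest other 26), the wild type at 5 dpi (7716, highest other 0), the mutant at 5 dpi (9468, highest other 0), and between the strains at 3 dpi (63, highest other 0) and 5 dpi (124, highest other 79). For roots alone over time 3 of 10 splits gave at least the real 1, and the highest other gave 38. For strain and time all 100 of 100 splits gave at least the real 0, and the highest other gave 460. Because the real count was 0, every split reaches it, so this share decides nothing. Splits that mixed the groups at both times gave at most 3. The 460 thus came from a split that kept the groups whole at 3 dpi, at 5 dpi or at both, which carries a strain difference into the interaction.

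Over 969 fungal genes scaled from 0 for the mutant to 1 for the wild type at 3 dpi, the library labelled wild type with the plant at 5 dpi, replicate 2, lay at 0.07, its group partner at 0.60 and the wild type alone at 0.13. Its best correlation was with the wild type alone, 0.953. It correlated with the mutant libraries at 0.928 to 0.943. With its group partner it correlated at 0.899, and with the wild type at 3 dpi at 0.848 and 0.814. All-or-none division of reads between near-identical genes was not tested. The fungal gene 55202 had 353, 229 and 353 CPM in the 3 shallowest libraries (0.974, 0.893 and 1.06 M counts), namely the mutant alone replicate 2, the mutant with the plant at 3 dpi replicate 2 and the library labelled wild type with the plant at 5 dpi replicate 2, and 0 in each of the other 8.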
